A study of Homo sapiens with 4 samples.

How the data were processed

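RNA of 4 samples was measured on Affymetrix arrays, 1 array for each of MET1 with miR-497, MET1 with empty vector, SCL-II with miR-497 and SCL-II with empty vector. The groups come from the sample titles. Per the submitters' processing notes, RMA and Partek were used, and no version is given in the sources used here. The background correction, filters and annotation of that step are not given in the sources used here either. The deposited values are 1 intensity per probe set on a linear scale, between 7.04 and 17339.8, with medians of 53.5, 53.6, 53.3 and 52.9 on the 4 arrays. RMA commonly returns log2 values, whereas these are linear, and the quartiles of the 4 arrays are nearly equal. How the linear scale was reached is not given in the sources used here. The analysis plan had assumed log2 values; log2 of the deposited intensity was taken and the planned tests kept. RMA commonly brings arrays to 1 distribution, so a shift of all genes in 1 direction would be removed, and low intensities hold background that shrinks fold changes of dim genes.

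The table holds 49394 probe sets. In the platform annotation 44993 had 1 gene symbol, 1832 several and 2569 none, and 101 were Affymetrix control probe sets. Only probe sets with 1 symbol were named, which gave 18132 genes. Of their 18134 gene IDs, 18112 were found in the RefSeq table of GRCh38.p14, 0 symbols changed, and that table was used only for names and for the order of neighbouring genes. Named genes at least 2-fold apart in a line with 1 array below its lower quartile of all probe sets, 8 in all, are given with a bound taken down to that quartile, which stands in for background since no detection call was used here. A gene was represented by its probe set with the highest mean over the arrays. Genes with a mean log2 value of at least 5.74, the median of all probe sets, were kept, which left 10742. Of 83 named genes with more than 1 probe set kept, 20 had probe sets at least 1 log2 unit apart in their difference in a line: ALDH1A3, ALDOC, AXL, CALD1, CD74, COL6A1, CTSH, CXCL1, CXCL8, EREG, GPC4, HMGA1, HMGA2, MMP13, MMP14, PTPRZ1, SOX9, SYT17, TPM1 and VEGFA. For these, the value given is that of the brightest probe set and the others differ from it. The widest spans were CTSH in MET1 (-5.33 to 0.32), AXL in MET1 (-3.55 to -0.46), VEGFA in MET1 (-2.24 to 0.02) and TPM1 in SCL-II (-1.85 to 0.31).

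The miR-497 effect was fitted with limma 3.58.1 in R 4.3.3 on log2 values with the construct and the line as additive terms, lmFit and eBayes, Benjamini-Hochberg adjustment over the genes kept and an adjusted p threshold of 0.05. The miR-497 and control arrays are paired by their cell line, taken from the labels. The residual, 1 degree of freedom per gene with a prior of 3.11, is the disagreement between the lines' effects. The p-values therefore measure the spread between 2 lines, not between replicate cultures, and assume that the 2 line effects are independent, which the closeness of the miR-497 arrays puts in doubt. The line term of the same fit compared MET1 with SCL-II. Within a line there is no test, and a size rule of 2-fold (1 on the log2 scale) was used.

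On simulated data with 10742 genes for the comparison of both lines, 100 of 100 genes changed by 1 and 100 of 100 changed by 2 on the log2 scale were recovered with array noise alone, with 11 false calls. With line-specific differences as large as observed, 0 of 100 and 86 of 100 were recovered with 0 false calls. These differences were added to the 2 controls in equal size and with opposite signs. They therefore cancel in the mean effect and enter only the residual, so they could not give false calls. The 0 does not bear on line-specific differences that do not cancel. No simulated case held 2 nearly identical miR-497 arrays that stand apart from both controls without an effect of miR-497. The false calls therefore do not bear on that case.

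The gene lists, the alternatives and the rule for named genes were fixed before the data were examined. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Of 31 lists, 29 had at least 3 measured members, and by chance 1.45 of 29 would lie outside the central 95% in a comparison; 12 did in MET1, 12 in SCL-II, 6 in both, 9 between the controls and 14 between the miR-497 arrays. Named genes were the 12 each way with the largest smaller difference of the lines, up to 12 each way past limma, the 6 highest and lowest in each line, the 5 genes with opposite differences whose smaller difference in size was largest, up to 10 each way past the line test, the 3 members of each list with the largest mean difference, CDH1, VIM, CDH2 and FN1, miR-497 and its host gene, and 2-fold members of the epithelial, mesenchymal and target lists. A further gene of this rule is not analysed here. Members of a list named outside this rule, such as IL1B, CCL20 and KRT15, were chosen after their values were seen.

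Median centring, a further quantile normalization, cyclic loess, no filter and a filter at the 75th percentile (8.03), the mean of probe sets, no line block, a trended robust prior, a threshold of 0.1 and a size of 1.5-fold were the alternatives. Arrays left out in turn, exchanged miR-497 arrays and the controls alone were added after the data were seen. The planned search for seed matches in 3′ untranslated regions was not run, since no transcript sequences were used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the other steps. All mapped columns were used and 0 were left unmapped.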

Results

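Messenger RNA levels were measured on 4 Affymetrix expression arrays in 2 established lines of cutaneous squamous cell carcinoma, MET1 and SCL-II. Each line carried either a plasmid for stable overexpression of miR-497, a microRNA that represses mRNAs carrying matches to its seed, or the empty vector as control. There was 1 array per group, so within a line no difference has a replicate check. By the labels, the 2 lines are the only replication of the miR-497 effect, and the likeness of the miR-497 arrays, given below, puts it in doubt. The series title places the study in the epithelial to mesenchymal transition of keratinocytes, and the comparisons ask how expression differed with miR-497 in each line and in both. The median probe-set intensity was 53.5 and 53.6 on the MET1 miR-497 and control arrays, and 53.3 and 52.9 on the SCL-II miR-497 and control arrays. The number of arrays limits the precision. In the annotation used, 0 probe sets carried the name of miR-497 or of its host transcript, so the overexpression itself was not checked on these arrays.

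The 2 arrays labelled miR-497 were closer to each other than any other pair, although they are labelled as different lines. Across the 10742 genes kept, their log2 values correlated at r = 0.995 and differed with an SD of 0.17, and 12 genes (0.112%) lay at least 2-fold apart. The 2 control arrays correlated at r = 0.947, with an SD of 0.58 and 622 genes at least 2-fold apart, of which 5 were also 2-fold apart between the miR-497 arrays. The MET1 miR-497 array correlated at r = 0.939 with the control of its own line and at r = 0.970 with the SCL-II control. The SCL-II miR-497 array correlated at r = 0.969 with its own control and at r = 0.936 with the MET1 control. These correlations run across genes, which are not independent replicates. Arrays are therefore named as labelled throughout, and the array labelled MET1 miR-497 or SCL-II miR-497 is meant wherever a difference in that line is given.

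**Figure D1:**
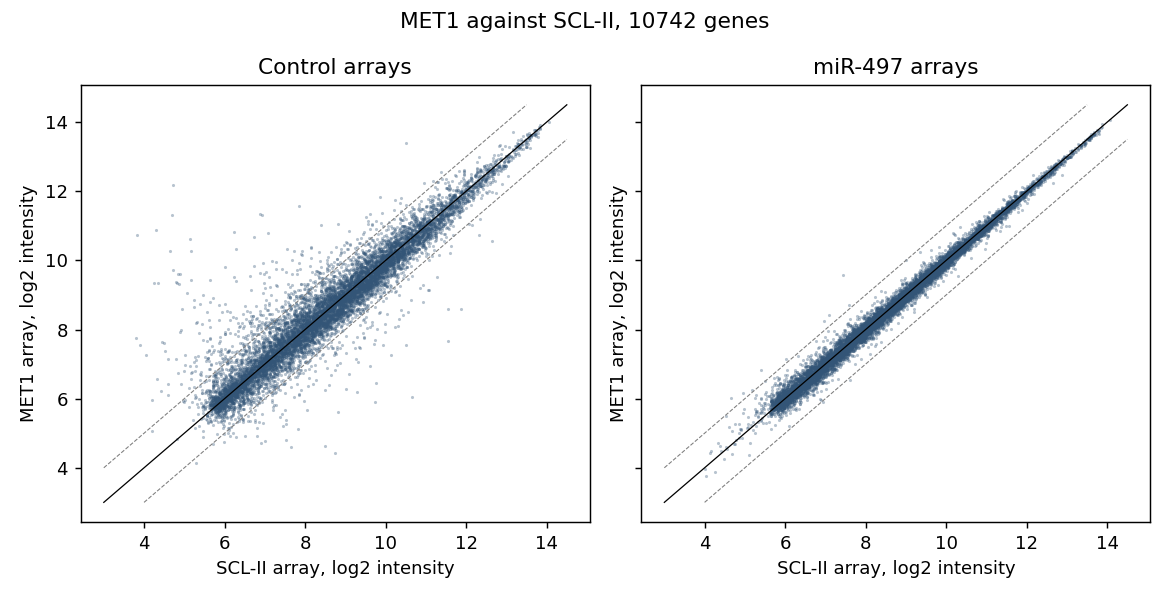
Each point is 1 of 10742 genes, with the log2 intensity on the SCL-II array on the x axis and on the MET1 array on the y axis, for the control arrays (left) and the miR-497 arrays (right). Dashed lines mark a 2-fold difference, which 622 genes reached between the controls and 12 between the miR-497 arrays.

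When both lines were tested together, 6 genes were lower with miR-497 and 0 were higher at an adjusted p under 0.05 (limma, line as a block). SMIM19, a small membrane protein gene, fell by 4.66 on the log2 scale (SE 0.15, limma adjusted p = 0.0381). MEX3C, an RNA-binding ubiquitin ligase, fell by 4.32 (SE 0.15, limma adjusted p = 0.0381). The acute-phase protein gene SAA1 fell by 3.42 and the neutrophil chemokine CXCL1 by 3.40, both with an SE of 0.15 and a limma adjusted p of 0.0492. TUSC3, a subunit of the complex that N-glycosylates proteins, fell by 3.17, and SMAD6, an inhibitory SMAD of BMP signalling, also fell by 3.17, with the same adjusted p. All 6 were lower in both lines: SMIM19 by a log2 difference of -4.57 in MET1 and -4.74 in SCL-II, MEX3C by -4.25 and -4.40, SAA1 by -3.51 and -3.34, CXCL1 by -3.50 and -3.31, TUSC3 by -3.23 and -3.11, and SMAD6 by -3.07 and -3.26. On both miR-497 arrays SMIM19 (3.87 and 4.25) and MEX3C (3.75 and 4.04) lay below the lower quartile of all probe sets (4.28), where intensities hold mostly background, so the sizes and SEs of these 2 are not exact. Measured only down to that quartile, SMIM19 was lower by at least 4.16 in MET1 and 4.72 in SCL-II, and MEX3C by at least 3.72 and 4.16. At an unadjusted limma p under 0.05, 813 genes were higher and 598 lower. The 2 miR-497 arrays are nearly identical, as given above, so the residual comes mostly from the difference between the controls. The SEs and p-values therefore do not measure agreement between 2 independent effects of miR-497. The fit has 1 residual degree of freedom per gene, and all 6 calls were lost with cyclic loess normalization, with no filter on low values or without the line as a block, and 2 were called after quantile normalization. With the mean of a gene's probe sets in place of the brightest, 34 genes were higher and 40 lower. A fit without the block called 0 and 0 on all arrays. With an array left out, such a fit has 1 array in a group and takes its spread from the other group alone. Without a control, that group is the nearly identical miR-497 arrays, so counts from these fits do not measure a response to miR-497.

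By size alone, 90 genes were at least 2-fold higher and 98 at least 2-fold lower with miR-497 in both lines. Independent lists would share 6.40 and 7.95 genes, but the nearly identical miR-497 arrays make the 2 lists not independent. When the miR-497 arrays were exchanged between the lines, which was tried after the data were seen, the count was 179 in place of 188, with 159 genes shared. The differences of the lines correlated across genes at r = 0.408 (Spearman's rho 0.358), and at r = 0.390 with the arrays exchanged. In these correlations the 2 differences share no array. With the mean of the miR-497 arrays as a common profile, set against each control, r was 0.438. Using the MET1 control as the common profile in its place gave r = 0.744, and using the SCL-II control gave r = 0.275.

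Among the genes 2-fold higher in both lines, the macrophage elastase gene MMP12 differed by 3.64 in MET1 and 2.41 in SCL-II (log2, miR-497 minus control). The selenium carrier gene SELENOP differed by 3.78 and 2.11, the heparan sulfate sulfotransferase gene HS6ST2 by 2.32 and 3.52, and the integrin ligand gene EDIL3 by 2.77 and 2.28. The stress-responsive NUPR1 differed by 2.19 and 3.32. SYT17 (2.86 and 2.19), PLSCR4 (2.55 and 2.15), RAB26 (2.13 and 2.53), NLGN4X (2.10 and at least 2.89), CPE (2.08 and 2.18), ACSM3 (2.42 and 2.05) and PLCB1 (2.36 and 2.03) complete the 12 with the largest smaller difference. For NLGN4X the SCL-II control lay below the lower quartile of all probe sets on its array, so that difference is given down to the quartile. None of these 12 passed the limma threshold over all genes. Among the 12 on the lower side, the 6 that passed it stood beside the BMP-responsive ID2 (-3.29, at least 3.27 in size, and -4.45), CXCL8 (-3.76 and -2.98), the proteoglycan enzyme gene XYLT1 (-4.72 and -2.49, at least 4.40 and 2.22 in size), the transcription factor gene SOX9 (-3.46 and -2.48), TENM3 (-3.20 and -2.47) and IL1A (-3.56 and -2.46), which did not pass. The sizes of XYLT1, and of ID2 in MET1, are lower bounds for the same reason, with the miR-497 arrays below that quartile.

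**Figure D2:**
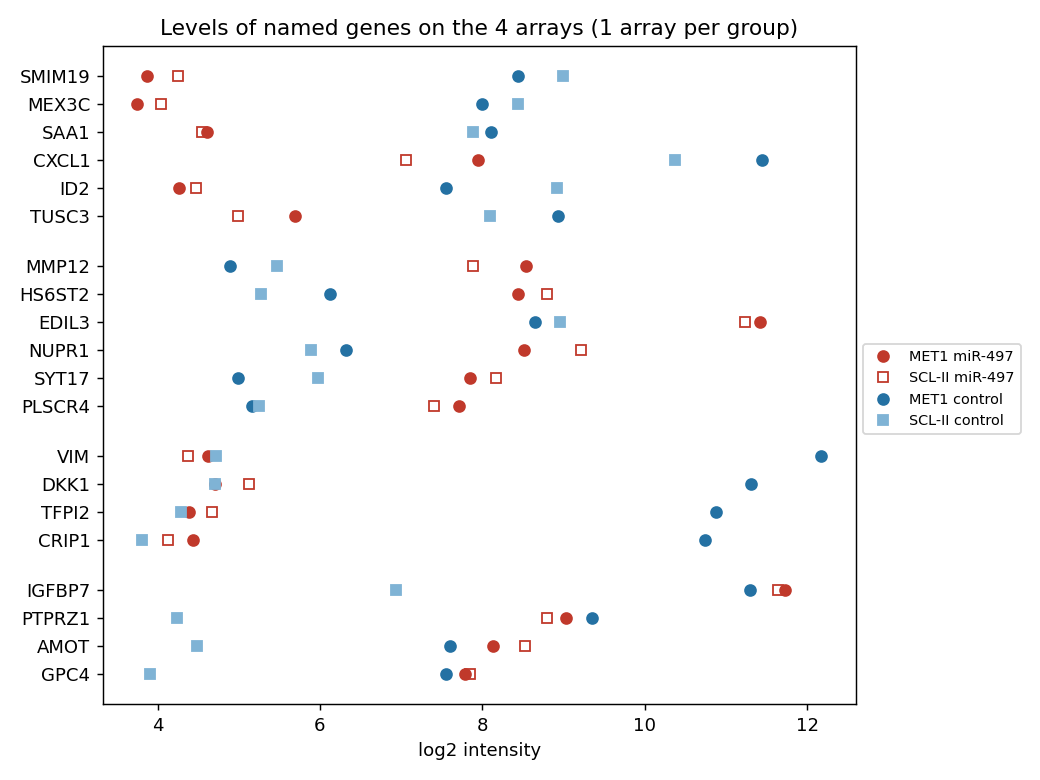
Log2 intensity (x axis) of named genes (y axis) on each of the 4 arrays, with 1 symbol per array and no error bars, since each group has 1 array. From top to bottom, the blocks hold genes lower in both lines, higher in both lines, lower in MET1 and higher in SCL-II; VIM is at 12.17 on the MET1 control array and between 4.37 and 4.72 on the other arrays.

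Genes of inflammatory cytokines and chemokines were lower with miR-497 in both lines. Of 19 measured, 9 were at least 2-fold lower in both, with list medians of -1.14 in MET1 and -0.88 in SCL-II, and 0 of 10000 random lists matched on mean expression lay lower in either line. CXCL1 passed the limma threshold over all genes, and 11 members, all lower, passed it adjusted over the list alone. The interleukin genes IL1A (-3.56 and -2.46) and IL1B (-2.15 and -1.48) and the chemokine genes CXCL8 (-3.76 and -2.98) and CCL20 (-2.81 and -1.88) were among the 9. Between the 2 control arrays this list had a median of 0.38, higher in MET1, and between the miR-497 arrays 0.14.

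Early response genes downstream of EGFR and AP-1 were also lower. Of 29 measured, 7 were 2-fold lower in both lines and 0 higher, with medians of -0.92 in MET1 and -0.41 in SCL-II, below which 0 of 10000 random lists lay in each line. The EGFR ligand gene EREG differed by -4.08 and -1.52, with its other probe set at -2.36 and -0.64, and the ERK phosphatase genes DUSP6 by -3.62 and -1.42 and DUSP4 by -3.18 and -1.31. Adjusted over the list alone 13 members passed, all lower, and over all genes 0 did. The MET1 control lay above the SCL-II control by a median of 0.69 for this list, with 11 members at least 2-fold apart, while 0 were 2-fold apart between the miR-497 arrays.

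TGF-beta and BMP response genes were lower in both lines. The medians of the 26 measured were -0.68 in MET1 and -0.65 in SCL-II, and 0 of 10000 random lists lay lower. In both lines 6 were 2-fold lower, among them ID2, SMAD6 and PMEPA1, a feedback inhibitor of TGF-beta signalling (-3.66 and -2.39). CCN2, a matricellular target of TGF-beta and YAP, went the other way (1.75 and 1.21). Over all genes 1 member, SMAD6, passed limma, and adjusted over the list alone 10 lower and 1 higher did. The controls differed by a median of 0.00 for this list and the miR-497 arrays by 0.10.

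Mesenchymal markers, the group closest to the title of the series, were lower at the median but not as 1 block. Of 28 measured, 4 were at least 2-fold lower in both lines and 1 was higher, and the medians of -0.50 in MET1 and -0.33 in SCL-II had 0 of 10000 random lists below them. The 4 were the fibronectin gene FN1 (-1.40 and -2.35), the activin subunit gene INHBA (-1.67 and -2.13), the matrix cross-linking enzyme gene LOXL2 (-2.44 and -1.12) and the receptor kinase gene AXL (-3.55 and -1.80), for which a further probe set differed by less. CCN2 was the 1 higher in both. The intermediate filament gene VIM, encoding vimentin, differed by -7.55 in MET1 and -0.35 in SCL-II. Its level was 12.17 on the MET1 control, 4.72 on the SCL-II control, and 4.62 and 4.37 on the MET1 and SCL-II miR-497 arrays, so the difference rests on the MET1 control array. The collagen gene COL5A2 (-3.88 and -0.56) and the gelatinase gene MMP2 (-4.20 and 0.02) had the same form. The N-cadherin gene CDH2 differed by -0.18 in MET1 and -1.35 in SCL-II, and THBS1 by -0.78 and -1.06. SPARC (2.18 and 0.47), CALD1 (1.13 and -0.37), S100A4 (0.70 and 1.25), MMP14 (-0.40 and 1.48) and COL6A1 (-1.15 and 0.49) were 2-fold apart in 1 line, with other probe sets of MMP14 down to 0.04 in SCL-II and of COL6A1 at -0.12 in MET1. No member passed limma over all genes; adjusted over the list alone, 7 lower and 2 higher did. The controls differed by a list median of 0.05, with 7 members 2-fold higher and 2 lower in MET1, and the miR-497 arrays by 0.13, with 0.

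Epithelial junction genes were slightly higher at the median. Their 38 measured members had medians of 0.17 in MET1 and 0.18 in SCL-II, above 9741 and 9998 of 10000 random lists; the MET1 median lay within the central 95% of random lists. The E-cadherin gene CDH1 differed by 0.34 and 0.06, from control levels of 11.76 and 12.01. S100A14 (1.02 and 1.10) was the 1 member 2-fold higher in both lines, and GRHL1, an epithelial transcription factor, followed at 1.06 and 0.94. These 2 genes passed limma adjusted over the list alone, and 0 members did over all genes. This list differed by a median of -0.09 between the controls and -0.04 between the miR-497 arrays. OVOL1 (-0.73 and -1.33) and PKP3 (-0.51 and -1.32) were lower, and ELF3 (1.24 and -0.07) and PERP (1.27 and 0.41) were 2-fold higher in MET1. Among 11 basal and simple keratins the medians were 0.06 and 0.23, with KRT15 2-fold higher (1.42 and 1.63) and KRT7 2-fold lower (-2.42 and -1.71) in both lines and KRT13 (5.08 and 0.73) and KRT14 (3.92 and 0.19) 2-fold higher in MET1; KRT15 and KRT7 passed limma adjusted over the list alone. The 10 measured genes of keratinocyte differentiation had medians of 0.26 and -0.14. The alarmin genes S100A8 (-1.45 and -1.66) and S100A9 (-2.10 and -1.90) were lower in both lines, and SERPINB3 (-2.72 and 0.08) in MET1. KLK5 (2.13 and -1.12) and TGM1 (1.15 and 0.37) were 2-fold higher in MET1. In SCL-II, KLK5 and IVL (0.41 and -1.16) were 2-fold lower.

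Genes of cell adhesion to the basement membrane and of the actin cytoskeleton were lower at the median. For the 26 integrin and basement membrane genes the medians were -0.30 in MET1 and -0.14 in SCL-II, with 0 and 15 of 10000 random lists lower. The type IV collagen gene COL4A2 differed by -1.96 and -1.63, while the nidogen genes NID1 (-4.49 and 0.53) and NID2 (-4.50 and 0.15) again rest on the MET1 control. For the 27 actin and YAP-related genes the medians were -0.14 and -0.14, with 259 and 37 of 10000 random lists lower, the first within the central 95%. The tropomyosin gene TPM2 differed by -5.88 and -0.06, AXL, also in this list, by -3.55 and -1.80, and TPM1 by -3.08 and -1.54, with probe sets of TPM1 between -1.85 and 0.31 in SCL-II. Adjusted over the list alone, 3 lower passed in the first list, and 1 higher and 2 lower in the second. The controls differed by medians of 0.18 and 0.07 for these lists, and the miR-497 arrays by 0.04 and 0.04.

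Published targets of miR-497 and its family, which a repressive microRNA would lower, differed little at the median. The 53 measured had medians of -0.05 in MET1 and -0.08 in SCL-II, with 967 and 77 of 10000 random lists lower, the first within the central 95%. In both lines 3 were at least 2-fold lower: the cyclin D1 gene CCND1 (-1.96 and -1.65), JUN (-2.13 and -1.24) and BDNF (-2.10 and -1.25). PDCD4, a translation inhibitor gene, was 2-fold higher in both (1.85 and 1.17). SMAD7 differed by -0.90 and -1.04. VEGFA (-1.79 and -0.30), IRS1 (-1.91 and -0.27), HMGA2 (-1.31 and -0.16) and HMGA1 (-1.22 and -0.25) were 2-fold lower in MET1, with probe sets of VEGFA, HMGA2 and HMGA1 that differed by much less. In all, 24 members were lower and 15 higher in both lines, whatever the size. No member passed limma over all genes, and adjusted over the list alone 4 lower and 1 higher did. The same list differed between the miR-497 arrays by a median of 0.05.

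Cell cycle genes, some of which, such as CCND1 and CDK6, are also in the list of published targets, differed little at the median. The 42 genes of G1 and S phase had medians of 0.15 and 0.00, and the 39 of G2 and M phase 0.10 and 0.01, all within the central 95% of random lists. CCND1 was the 1 member of either list at least 2-fold apart in both lines, while CDK6 differed by -0.98 and -0.51, E2F8 by -0.25 and -0.65, CDC25C by 0.87 and 0.21, NUSAP1 by 0.48 and 0.36 and CDC25B by -0.63 and -0.16. CCND1 passed limma adjusted over the list of G1 and S phase genes alone, and 0 members of the G2 and M list did. The list of G1 and S phase differed by a median of -0.32 between the controls and -0.13 between the miR-497 arrays, MET1 minus SCL-II, with 0 of 10000 random lists lower in each. The list of G2 and M phase differed by -0.09 and 0.01. Ribosomal protein genes (medians 0.00 and 0.01) and housekeeping genes (0.05 and 0.04) served as lists not thought to respond, and none of their members was 2-fold apart in either line.

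**Figure D3:**
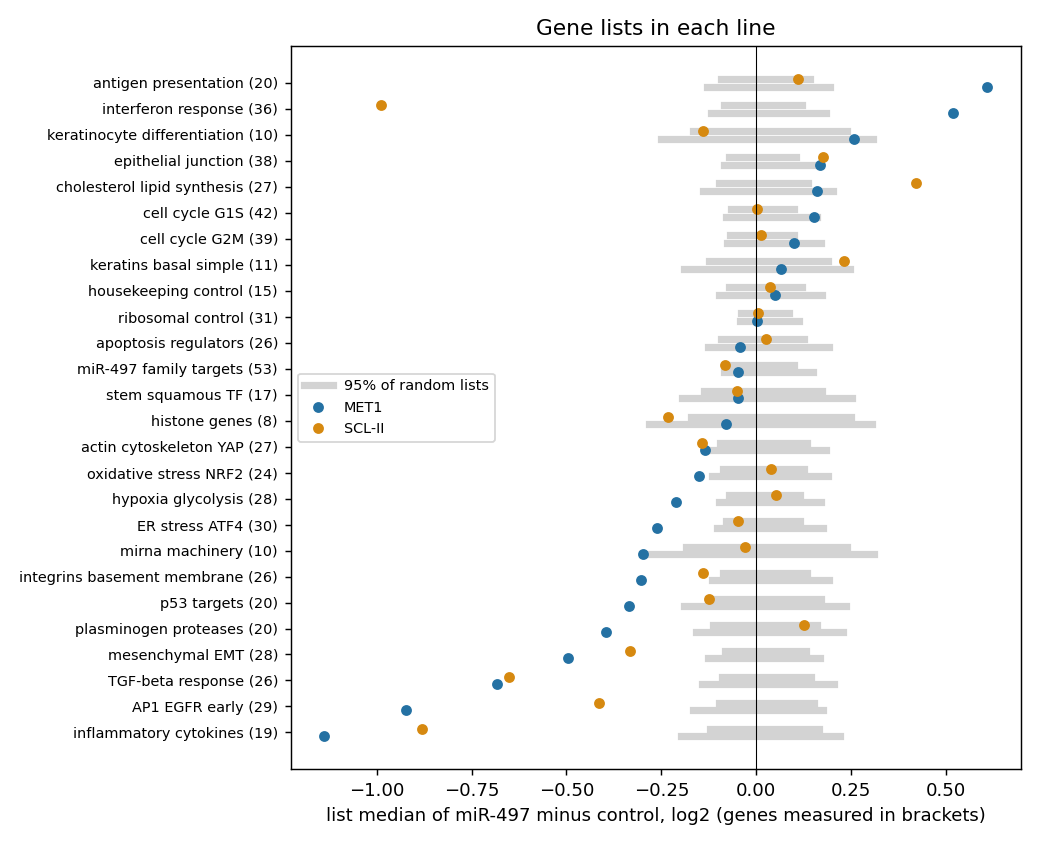
Median log2 difference, miR-497 minus control (x axis), of each gene list with at least 8 measured genes (y axis), in MET1 (blue) and SCL-II (orange). Grey bars span the central 95% of 10000 random lists matched on mean expression; the inflammatory cytokine list lies at -1.14 and -0.88 and the interferon list at 0.52 and -0.99.

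In MET1 alone, 320 genes were at least 2-fold higher and 429 at least 2-fold lower on the miR-497 array. The epithelial keratin genes KRT13 and KRT14, PPP2R2B (3.73, against -1.18 in SCL-II) and the collagenase gene MMP13 (3.63) led the higher side with SELENOP and MMP12. VIM (-7.55), the WNT antagonist gene DKK1 (-6.60), the protease inhibitor gene TFPI2 (-6.48), CRIP1 (-6.31), TPM2 (-5.88) and the cathepsin gene CTSH (-5.33) led the lower side. A further probe set of CTSH did not follow. For VIM, DKK1, TFPI2, CRIP1 and TPM2 the SCL-II difference was -0.35, 0.42, 0.38, 0.32 and -0.06, with the SCL-II control near the level of the miR-497 arrays.

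In SCL-II alone, 215 genes were at least 2-fold higher and 199 at least 2-fold lower. The secreted factor gene IGFBP7 (4.71), the receptor phosphatase gene PTPRZ1 (4.56), AMOT, a YAP-binding protein gene (4.04), the glypican gene GPC4 (3.94) and GAL3ST4 (3.74) were, with HS6ST2, the 6 with the highest measured differences. On the SCL-II control PTPRZ1, GPC4 and GAL3ST4 lay below the lower quartile of all probe sets, so they have no firm order, and down to that quartile they were higher by at least 4.53, 3.57 and 3.25. In MET1 these 5 differed by 0.42, -0.32, 0.53, 0.24 and -0.25, with the MET1 control near the miR-497 arrays. On the lower side, TRIM31 (-3.43, against -0.49 in MET1) joined genes lower in both lines, namely SMIM19, ID2, MEX3C, SAA1 and CXCL1.

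Interferon-stimulated genes differed from the control with opposite signs in the lines, whose controls already differed. Their 36 measured members had a median of 0.52 in MET1, above 10000 of 10000 random lists, and -0.99 in SCL-II, below which 0 lay. Between the controls the median was -1.54, lower in MET1, with 27 members at least 2-fold lower and 0 higher, and between the miR-497 arrays it was -0.09 with 0 members 2-fold apart. IFI6 differed by 1.59 and -1.70 and IFI44L by 1.30 and -2.24. IFI27 (-1.81 and -2.03) and ISG20 (-1.28 and -1.23) were lower in both lines and passed limma adjusted over the list alone, while IRF7, a transcription factor of the response, differed by -0.21 and -1.82. CFI (2.53 and -1.64), EPDR1 (1.39 and -1.75) and SLC25A38 (-1.78 and 1.47), outside this list, were the other genes named as opposite, by the smaller of their 2 differences. The difference between the lines was not tested. For the interferon list, whose miR-497 arrays were nearly equal, the opposite signs follow from the difference between the controls.

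The comparison of MET1 with SCL-II over both constructs called 0 genes (limma adjusted p under 0.05, with miR-497 as a term). At an unadjusted limma p under 0.05, 129 were higher and 67 lower in MET1. With the miR-497 arrays nearly equal, the line effect and its residual both come from the difference between the controls. A large difference raises both, so the 0 calls do not show that the lines are alike. Between the controls alone, 429 genes were at least 2-fold higher and 193 lower in MET1, VIM, DKK1, TFPI2 and CRIP1 among the higher and KRT13 and KRT14 among the lower. In 0 genes were both MET1 arrays at least 1 log2 unit above or below both SCL-II arrays. The same rule separated the miR-497 arrays from the controls in 78 higher and 81 lower genes. Along the autosomes, medians over 511 windows of neighbouring genes, 490 of them with 20 genes and the others with up to 38, reached 0.3 or more on the log2 scale either way between the controls in 31 windows higher and 14 lower in MET1, and in 0 windows between the miR-497 arrays.

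**Figure D4:**
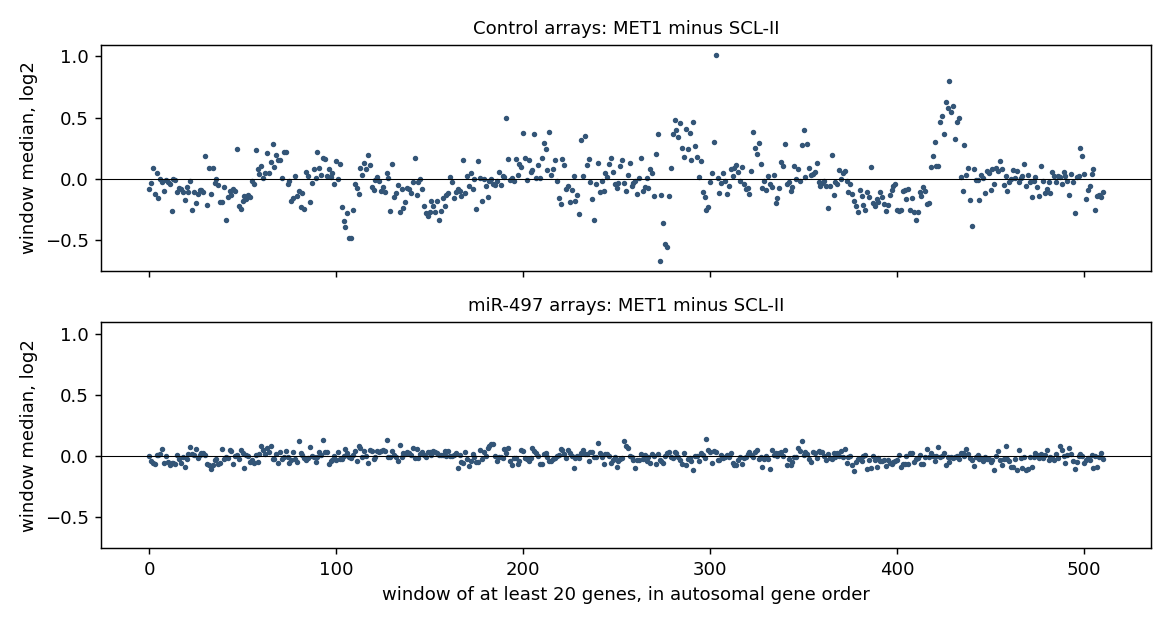
Each point is the median log2 difference, MET1 minus SCL-II (y axis), over a window of 20 to 38 neighbouring genes, placed in autosomal gene order (x axis, window number), for the control arrays (top) and the miR-497 arrays (bottom). Of 511 windows, 31 lie at or above 0.3 and 14 at or below -0.3 between the controls, and 0 do between the miR-497 arrays.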

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

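The correlation test of a single profile, the correlation of neighbouring windows and the tests of probe sets by gene and over 5986 genes were chosen only after the results were seen.

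Several results differed between the lines because the MET1 difference was positive and the SCL-II difference negative, or the reverse. None of these differences between the lines was tested, since each rests on 1 array per group. CFI differed by 2.53 in MET1 and -1.64 in SCL-II, IFI6 by 1.59 and -1.70, SLC25A38 by -1.78 and 1.47, EPDR1 by 1.39 and -1.75, and IFI44L by 1.30 and -2.24. The interferon list had a median of 0.52 in MET1 and -0.99 in SCL-II. On the miR-497 arrays the list lay between the 2 controls. Its median difference, MET1 minus SCL-II, was -1.54 between the controls and -0.09 between the miR-497 arrays. The opposite signs of this list follow from the difference between the controls and do not show a response particular to 1 line.

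The first pattern is that the 2 miR-497 arrays lie close together although they carry the labels of 2 lines. If miR-497 had drawn both lines to a shared state, regional differences that follow DNA copy number should remain, but the slope of the miR-497 arrays' window differences on the controls' was 0.00315 (bootstrap 95% interval -0.0156 to 0.0212), which argues against it. If 1 RNA had been hybridised to both arrays, other probe sets should not follow the genes that differ. Among genes 2-fold apart 4 of 5 did, though 3 belong to FYB1. By gene it is 2 of 3 (exact 95% interval 0.0943 to 0.992), too few to decide. Over 5986 genes the other probe sets followed at r = 0.465, against at most 0.043 in 1000 shufflings. This argues against 1 labelled RNA on both arrays, except that probe sets of a gene that share probes were not set apart. Separate labellings of 1 RNA could move all probe sets of a gene together, so they are not excluded. Of 29 gene lists, 14 differed beyond 95% of random lists against 1.45 by chance. That count treats genes as independent and had no rule set beforehand, so it does not decide. That both arrays hold cells of a single line is consistent with the slope of 0.00315 and remains a hypothesis; a mislabelled culture, a cross-contaminated line and 2 samples of 1 transfected population all remain open, and no DNA was measured.

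The second pattern is that each miR-497 array stands apart from the control of its own line, and the biological explanation, from the design, is that miR-497 acts in an unchanged genome. In MET1 the SD of window medians was 1.97 times the mean of 1000 shuffled gene orders, and in SCL-II 1.82 times, both above every shuffle and above the 1.5 times set beforehand, whereas an effect of miR-497 on genes spread over the genome should stay within the shuffles. Neighbouring windows correlated at r = 0.636 in MET1 and 0.479 in SCL-II, against 0.276 between the miR-497 arrays. The window SD of the miR-497 arrays, 1.23 times the shuffled mean, was also above every shuffle, so a place beyond the shuffles does not decide. Over single genes the differences had an SD of 0.17 between the miR-497 arrays, against 0.62 in MET1 and 0.45 in SCL-II. With such unequal differences, 1.23 is not a ceiling for what co-regulated neighbours could give in a line. The 1.5 times was not calibrated for them, so the larger ratios do not decide either. Whether co-regulated neighbouring genes or copy number give the ratio of 1.23 was not tested, so a part of the regional pattern in each line may not be copy number. The lines were not alike in this pattern. In SCL-II 3 windows lay at 0.3 or above and 7 at -0.3 or below, against 25 and 26 in MET1. The SCL-II ratio rests largely on a few windows, with medians as far as -0.86 and 0.74, and was not computed without them. Most of the low windows in SCL-II lie in a single run of neighbouring windows. Their medians, in gene order, were -0.82, -0.22, -0.81, -0.86, -0.69, -0.85 and -0.54. A response to miR-497, with or without a difference in genome, remains open for both lines.

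The third pattern is that 188 genes moved 2-fold the same way in both lines. A single profile set against 2 different controls may give such sharing: the correlation was 0.438 with the mean miR-497 profile as the common one, below the 0.744 found with the MET1 control in its place, which lies furthest from the others, and above the 0.275 found with the SCL-II control, so the test does not decide. The explanation from the design, that miR-497 moves the same genes in each line, stays untested, because with 2 nearly identical miR-497 arrays it and a difference of origin predict the same sharing. The 6 genes called by limma rest on the same sharing, as does the agreement between the lines of those list medians that have the same sign.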

How the results depend on the processing

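Arrays left out, exchanged miR-497 arrays and controls alone were chosen after the data were seen. The limma count of 0 higher genes became 4 with the strict filter, 34 with the mean of probe sets and 22 at a threshold of 0.1. The count of 6 lower became 2 with quantile normalization, 0 with cyclic loess, 0 with no filter, 0 with no replicate block, 40 with the mean of probe sets and 28 at a threshold of 0.1. Leaving out each array, in a fit that also drops the line, and so is to be set against 0 and 0, and that assumes a lone array varies like the other group, gave 0 to 1547 higher and 0 to 1420 lower: 480 and 351 without the MET1 control, 1547 and 1420 without the SCL-II control, and 0 and 0 without either miR-497 array. Median centring and the trended prior kept the counts at 0 and 6. The line comparison called 0 under each alternative run, an outcome that the nearly equal miR-497 arrays make likely however far the controls differ.

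The 2-fold counts in MET1 were 130 higher and 160 lower with the strict filter, 187 and 233 with the mean of probe sets, and 994 and 1058 at 1.5-fold. In SCL-II they were 72 and 82, 109 higher, and 668 and 523. For both lines they were 29 and 35, 43 and 61, and 290 and 225. The strict filter and the mean test fewer genes (6281 and 9033 of 10742), which accounts for part of the drop. The mean of both constructs put 120 genes 2-fold higher and 37 lower in MET1 than in SCL-II, and the controls alone 429 and 193. Of 394 alternatives for list medians, 363 moved by less than 0.5 of the width of the random lists' central range, 29 by more and 2 changed sign: the interferon median, 0.52 without SCL-II and -0.99 without MET1, and the histone median in SCL-II, 0.093 with the mean of probe sets. The cause was not tested. Of 1528 alternatives for named genes, 1442 moved little, 86 moved more and 0 changed sign where 2-fold. Seed matches were not run. Values near the lower end of the intensity range hold mostly background.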

Other observations

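The genes that mark 1 array were looked for only after the data were seen, and are given as values.

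Antigen presentation genes were higher at the median on the MET1 miR-497 array. Their 20 measured members had medians of 0.61 in MET1, above 10000 of 10000 random lists, and 0.11 in SCL-II, above 9356 and within the central 95%. The MET1 control itself lay below the SCL-II control by a list median of -0.27, with 6 of 10000 random lists lower, and the miR-497 arrays differed by 0.06. The class II genes HLA-DRA (1.78 and 1.05), CD74 (1.69 and 1.05) and HLA-DMA (1.68 and 0.54) differed most, and 2 members passed limma adjusted over the list alone. Cholesterol and lipid synthesis genes had medians of 0.16 and 0.42, above 9321 and 10000 of 10000 random lists, with the desaturase gene FADS1 at -0.56 and 2.41, TM7SF2 at 0.96 and 0.88 and IDI1 at 0.82 and 0.85. The NRF2 list (medians -0.15 and 0.04, with 96 and 6525 of 10000 random lists lower) held aldo-keto reductase genes that went opposite ways to each other: AKR1B10 differed by 2.14 and 1.59, AKR1C1 by -2.09 and -2.24 and AKR1C2 by -1.32 and -0.22. Among squamous and stem cell factors (medians -0.05 and -0.05), SOX2 differed by 1.04 and 1.38, ALDH1A3 by -2.04 and -1.51 and MYC by -2.02 and -0.78.

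For 3 stress and protease lists the controls already stood apart: MET1 lay above SCL-II by a median of 0.21 for hypoxia and glycolysis, 0.15 for ATF4 and 0.19 for plasminogen and proteases, above 9991, 9938 and 9863 of 10000 random lists. Between the miR-497 arrays these medians were -0.03, -0.04 and 0.23, above 2272, 1183 and 10000 of 10000 random lists. The plasminogen and protease list thus stood apart between the miR-497 arrays as well. The values that follow are miR-497 minus control, and no difference between the lines was tested. The p53 target list, 0.14 apart between the controls, had medians of -0.33 and -0.12, led by TP53I3 (-1.77 and -0.58), PLK2 (-0.74 and -1.40, with a probe set at 0.00 in MET1) and FAS (-0.59 and -0.99). The hypoxia and glycolysis list had medians of -0.21 and 0.05, with 7 and 7479 of 10000 random lists lower. In it, HK2 was at -1.29 and -0.59 and ALDOC at 0.37 and 1.19, where the probe sets of ALDOC in SCL-II went down to 0.13. The ATF4 list had medians of -0.26 and -0.05, with 1 and 914 of 10000 random lists lower. In it, ATF3 was at 1.24 and 0.44, SLC3A2 at -0.90 and -0.58 and ATF5 at -0.82 and -0.57. The plasminogen and protease list had medians of -0.39 and 0.12, with 0 and 9372 of 10000 random lists lower, but its members went both ways. In MET1 6 members were 2-fold higher and 4 lower. In both lines 2 were 2-fold higher, MMP12 (3.64 and 2.41) and MMP7 (2.47 and 1.54), and 1 was lower, SERPINE2 (-1.08 and -1.24). MMP2 differed by -4.20 and 0.02. Apoptosis regulators (-0.04 and 0.03), with TNFSF10 at 1.56 and 0.46 and BIK at -0.50 and -0.83, microRNA machinery (-0.30 and -0.03), with TNRC6C at -1.36 and 0.09, TNRC6B at 0.18 and 0.87 and TARBP2 at -0.59 and -0.39, and histone genes (-0.08 and -0.23), with H2AC11 at -0.51 and -0.90, H2BC5 at -0.83 and -0.25 and H2AC8 at -0.13 and -0.63, had no member 2-fold the same way in both lines. The histone median in SCL-II had 70 of 10000 random lists lower, though it changed sign with the mean of probe sets. Between the miR-497 arrays the 8 measured histone genes had a median of 0.33, higher on the array labelled MET1 and above 10000 of 10000 random lists.

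Markers of other cell types were mostly not measured above the filter. Melanocyte (0.07 and 0.17, with MITF at -0.41 and -0.80), endothelial (-0.06 and 0.21, with CDH5 at 0.99 and 0.25) and glandular epithelial markers (0.14 and 0.06, with MUC1 at 0.14 and 0.54) had 3, 3 and 5 measured members and medians within the central 95% of random lists. Fibroblast and leukocyte markers had 2 each, too few for a median; FBLN1 differed by 1.79 and 1.03, COL1A1 by 0.34 and -0.10, CD68 by -0.23 and 0.10 and TYROBP by -0.15 and 0.26.

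Some genes marked 1 array. On the MET1 control, 25 genes lay at least 3 log2 units above the other arrays, which were within 1 unit of each other, and 2, KRT13 and KRT14, lay as far below. The 25 held VIM, DKK1, TFPI2, CRIP1, TPM2, CTSH, NID1, NID2 and MMP2. On the SCL-II control 1 gene, ECM2, lay above (8.82 against 5.61 on each of the other arrays) and 5 lay below, IGFBP7, PTPRZ1, GAL3ST4, GPC4 and AMOT. The miR-497 arrays had 0 such genes. Between them, KRT4 (-1.06) and KIF26A (-1.05) were lower on the array labelled MET1, and HINT3 (2.15), IL7 (1.44), DNER (1.36), FYB1 (1.32), MMP10 (1.28), ETV1 (1.21), CFI (1.14), COXFA4L3 (1.12), PDZK1IP1 (1.06) and LRP12 (1.02) were higher; the other probe sets of FYB1 (3 of 3) and IL7 (1 of 1) differed the same way, and that of HINT3 did not. The Affymetrix control probe sets differed with an SD of 0.13 between the miR-497 arrays and 0.28 between the controls.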
